A study of Gallus gallus with 6 samples.

How the data were processed

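RNA-seq was done on macrophages sorted by flow cytometry with the KUL01 antibody from the ileum of broilers, 3 libraries from birds injected with LPS and 3 from birds that also received L. reuteri by gavage. Per the labels' protocols, libraries were prepared from polyadenylated RNA captured on oligo(dT) beads. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, without saying how each was used. The genome build is not given in the sources used here, so coordinates are printed as the deposited table lists them. Strand handling in the counting is not given either, so genes that overlap another gene on the opposite strand have uncertain values.

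The deposited table holds, per the file headers, a whole-number count and an FPKM value for each gene and library, where FPKM is fragments per kilobase scaled to mapped fragments, as the authors computed it. The counts were deposited without normalization. FPKM was checked against the counts of the LPS libraries: for the 9889 genes with at least 100 counts in each, the ratio of count to FPKM, taken relative to LPS1 and to each library's median, lay within 1% of 1 in 99.4% of cases. The 3 FPKM columns of the LPS+LR21 group were not used, because their names match no single sample and that group's counts were already used. After the data had been seen, FPKM was therefore recomputed for all 6 libraries from the counts, the column totals and the gene lengths implied by the deposited LPS columns, and FPKM in the text means these values. For the same 9889 genes all of them lay within 5% of the deposited LPS values. The 1226 genes without a deposited FPKM above 0 in the LPS libraries, 19 of them tested, have no FPKM here. The table has 27656 genes, 16246 of them protein-coding and 10579 long noncoding RNAs, and 14338 have no symbol. Of 12422 genes with an Entrez identifier, 12303 matched the RefSeq gene table of assembly GRCg7b, which was used only for synonyms.

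LPS columns were matched to samples by group and number. The numbers of the LPS+LR21 columns LR1_2, LR3 and LR4, taken as a set, are not those of the sample titles, so the columns were used as 3 replicates of the group with no further identity, and whether LR1_2 is a pool is not stated. The labels do not say that libraries came from separate birds, so p-values measure only the spread between these samples, which may be technical. Each pair of libraries differed by more than sampling noise, with a lowest chi-square statistic per degree of freedom of 117. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.850 to 0.869 within LPS, 0.829 to 0.892 within LPS+LR21 and 0.808 to 0.855 between the groups. By the chi-square statistic per degree of freedom, LR3 was nearer to the LPS libraries than to its own group. The values were 232, 198 and 162 against LPS1, LPS2 and LPS3, and 523 and 353 against LR1_2 and LR4.

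Total counts ranged from 31284679 to 45492503. Mitochondrial genes took 12.1% to 17.7% of counts, with LR4 highest, and between 18811 genes (LR3) and 24539 genes (LR4) had a count. TMM factors lay between 0.928 and 1.19. The common biological coefficient of variation was 0.773.

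The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr kept 20745 genes, TMM factors were applied, and glmQLFit and glmQLFTest compared the groups with no covariate. Adjusted p-values are Benjamini-Hochberg values over the tested genes, two-sided, with a threshold of 0.05. The design named limma on FPKM for a table without counts and this test for a table with them, and the table had them. Log2 fold changes and standard errors come from this fit, the standard error being the fold change divided by the square root of the F statistic, and means and SDs are of FPKM. A gene with no count in a whole group is given as at least the fold between the other group's mean and a floor of 3 counts per library.

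Before the data were examined, 30 gene lists were fixed (1375 symbols, 1083 of them in the table), covering macrophage functions, niche signals, metabolism, stress and the other cell types an ileal sort could hold. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 30 lists; camera with an estimated correlation and fry were run beside it. All 30 had at least 5 tested members. Of the 63 epithelial markers, 2 are also in another list, as are 16 of the 28 macrophage identity genes. After the data had been seen, gene ontology terms in the table with at least 5 tested genes were tested by a one-sided Fisher's exact test against 10133 annotated tested genes.

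Genes were named by a rule fixed beforehand: the 10 largest called changes in each direction with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between groups (10 passed in each direction, so none was filled in by unadjusted p); the members of smallest p in each list; the macrophage genes CSF1R, IL10, IL1B, IL6, NOS2, TGFB1, CD163, TLR4 and the mannose receptor family; and measured niche ligands. CD163 has no row under that symbol and is not analysed here. EPCAM, APOB, MTTP, SLC5A1, FABP1, FABP2, OLFM4 and LGR5 were named after their values were seen. Some genes that the rule names are not reported here.

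The steps were tested on simulated counts for the same 20745 genes, drawn from their real levels, library sizes and dispersions, with 200 changed genes of at least 5 CPM. In this simulation of LPS+LR21 against LPS, edgeR called 0% of 67 genes changed 2-fold, 37.3% of 67 changed 4-fold and 92.4% of 66 changed 16-fold, and 4 of 20545 unchanged genes. DESeq2 called 10.4%, 73.1% and 100% of them and 127 unchanged genes. With no gene changed, edgeR called 0. A planted list and a planted ontology term were each called, and 0 of 29 other lists and 0 of 100 other terms. Genes were drawn independently there, whereas the estimated correlation within the real epithelial list was 0.525. The 0 of 29 therefore does not show how often camera at the preset correlation wrongly calls lists of correlated genes.

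Alternatives fixed beforehand were no filter, a mean of at least 5 FPKM, library totals without TMM factors, DESeq2 size factors, robust estimation, limma-voom with quantile normalization or with library quality weights, limma-trend on log2(FPKM + 0.1), DESeq2 1.42.0, each library left out, and unadjusted p. Because edgeR takes neither quantile-normalized values nor library weights, plain limma-voom was added as their reference. After the data had been seen, limma-trend on log2(FPKM + 1), LR3 as the only LPS+LR21 library, the epithelial score (mean log2 CPM of the epithelial markers) as a covariate and scaling to the macrophage identity genes were added. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).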

Results

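Transcriptomes were measured by RNA-seq of macrophages sorted from the ileum of broiler chickens by flow cytometry with KUL01, an antibody against a chicken mannose receptor that is widely used to label macrophages. The birds had been injected with lipopolysaccharide (LPS), a bacterial cell-wall component that provokes inflammation, and 1 of the 2 groups also received a gavage of Lactobacillus reuteri, a lactic acid bacterium of the gut. There were 3 libraries of the LPS group and 3 of the LPS plus L. reuteri group, which is called LPS+LR21 as in the labels. The LPS+LR21 libraries are named here by their columns, LR1_2, LR3 and LR4. Total counts per library were 40542094, 38492909 and 44786499 in the LPS group, 45492503 in LR1_2, 40767345 in LR3 and 31284679 in LR4. A floor of 3 counts corresponded to 0.0659 to 0.0959 CPM (counts scaled to the library's total), and it covers counting error only.

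The question posed was how expression in the ileal macrophages of LPS-injected broilers differed when L. reuteri was given, with particular interest in signals passing between macrophages and intestinal stem cells. Of 63 epithelial cell markers 19 rose in the LPS+LR21 libraries and 44 did not pass, and genes that mark macrophages and lysosomes had lower fitted values there. The epithelial list was called higher by camera at the preset correlation (adjusted p = 1.09e-50), but not with an estimated correlation (adjusted p = 0.229) or by fry (adjusted p = 0.0925). Of 20745 genes tested, 202 rose and 17 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05; smallest adjusted p 0.0344), so that 92.2% of the changed genes were higher (80.7% of 135 with quantile normalization in limma-voom). The share differed between settings: it was 73.6% of 1361 changed genes with DESeq2, 75.1% of 434 at a mean of at least 5 FPKM, 55.8% of 1945 without LR3 and 54.2% of 1956 with library quality weights in limma-voom. It was 93.5% of 321 with library totals. Scaled to the macrophage identity genes, a setting chosen after the data had been seen, it was 99.9% of 4784. The median log2 fold change was 2.56 among the risen genes and -2.02 among the fallen genes. Genes for inflammatory cytokines and for ligands of the stem-cell niche did not pass the test one by one.

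**Figure D1:**
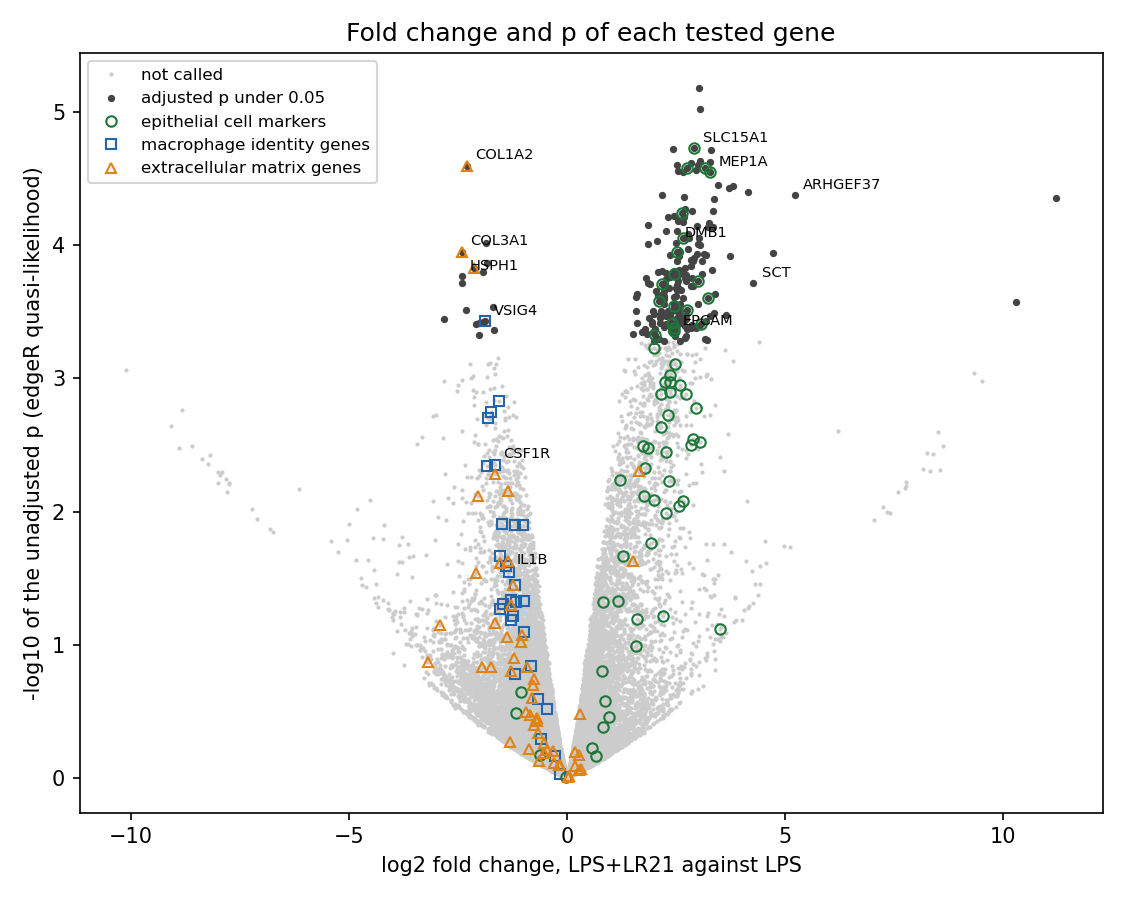
Each point is 1 of the 20745 tested genes, with the log2 fold change of LPS+LR21 against LPS on the x axis and -log10 of the unadjusted p on the y axis; dark points passed the adjusted threshold, and open symbols mark members of 3 gene lists. Of the epithelial markers 59 of 63 lie to the right and all 28 macrophage identity genes to the left of 0; points at the far left and right are genes with few or no counts in 1 group, whose fitted fold changes are not reliable sizes.

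The genes with the largest called increases included several of the enterocyte surface. ARHGEF37, a guanine nucleotide exchange factor gene (ENSGALG00010008217, chromosome 13, 8043385 to 8055575, minus strand), had 0.124 ± 0.0489 FPKM in the LPS libraries and 5.20 ± 3.62 in the LPS+LR21 libraries (SD, n = 3 each), a log2 fold change of 5.22 ± 0.73 (SE). SCT, which encodes the gut hormone secretin, rose by 4.28 on the log2 scale and VTN, which encodes the adhesion glycoprotein vitronectin, by 3.72. ENPP7, an alkaline sphingomyelinase of the intestinal brush border, had 2.84 ± 2.28 FPKM in the LPS libraries and 39.5 ± 14.2 in the LPS+LR21 libraries. CPO, a brush-border carboxypeptidase (ENSGALG00010025855, chromosome 7, 11971431 to 11984891, minus strand), had 24.7 ± 8.17 FPKM in the LPS libraries and 288 ± 143 in the LPS+LR21 libraries. SLC27A2, a very-long-chain acyl-CoA synthetase, had a log2 fold change of 3.35 ± 0.48 (SE). TSPAN7, a tetraspanin, the oxidative-stress response gene OSGIN1, the ectonucleotidase gene ENPP3 and the claudin gene CLDN23 rose by 3.38, 3.32, 3.29 and 3.28. Adjusted p of these 10 genes lay between 0.0344 and 0.0435 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were chosen among genes whose groups did not overlap. Over all tested genes the groups did not overlap for 19.4%, where chance gives 10%.

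Of the 63 measured epithelial cell markers, 19 rose, none fell and 44 did not pass the test; adjusted over the list alone, 47 rose. The list's median log2 fold change was 2.27, and its camera adjusted p was 1.09e-50 (adjusted p = 0.229 with an estimated correlation). SLC15A1, the intestinal peptide transporter PepT1 (ENSGALG00010005851, chromosome 1, 144823021 to 144845173, plus strand), had 10.2 ± 2.46 FPKM in the LPS libraries and 87.9 ± 40.8 in the LPS+LR21 libraries. MEP1A (ENSGALG00010008307, chromosome 3, 109660691 to 109674924, plus strand) and MEP1B encode the subunits of the brush-border protease meprin, and they rose by 3.28 and 3.18 on the log2 scale. The neutral amino acid transporter gene SLC6A19 rose by 2.77. All 4 had an adjusted p of 0.0344 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. EPCAM, the epithelial cell adhesion molecule, was named after its values were seen: it had 82.4 ± 17.7 FPKM in the LPS libraries and 510.5 ± 269.6 in the LPS+LR21 libraries (SD, n = 3 each) and adjusted p = 0.0449. Epithelial transcripts were also present in the LPS libraries, where 50 of the 63 markers had a mean of at least 1 FPKM. The list's median against the LPS mean was 2.94 in LR1_2, 1.15 in LR3 and 2.37 in LR4, and 196 of the 202 risen genes had their lowest LPS+LR21 value in LR3. In the gene ontology annotation of the table, 15 risen genes belonged to the apical plasma membrane against 1.74 expected (adjusted p = 7.19e-07, one-sided Fisher's exact test over 4503 terms), and 7 belonged to the brush border against 0.437 expected (adjusted p = 0.000459). In all 8 terms were enriched among the risen genes and none among the 17 fallen genes. This enrichment was added after the data had been seen. Fisher's test treats genes as independent, whereas the risen genes varied together across libraries, so its p-values may be too small.

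**Figure D2:**
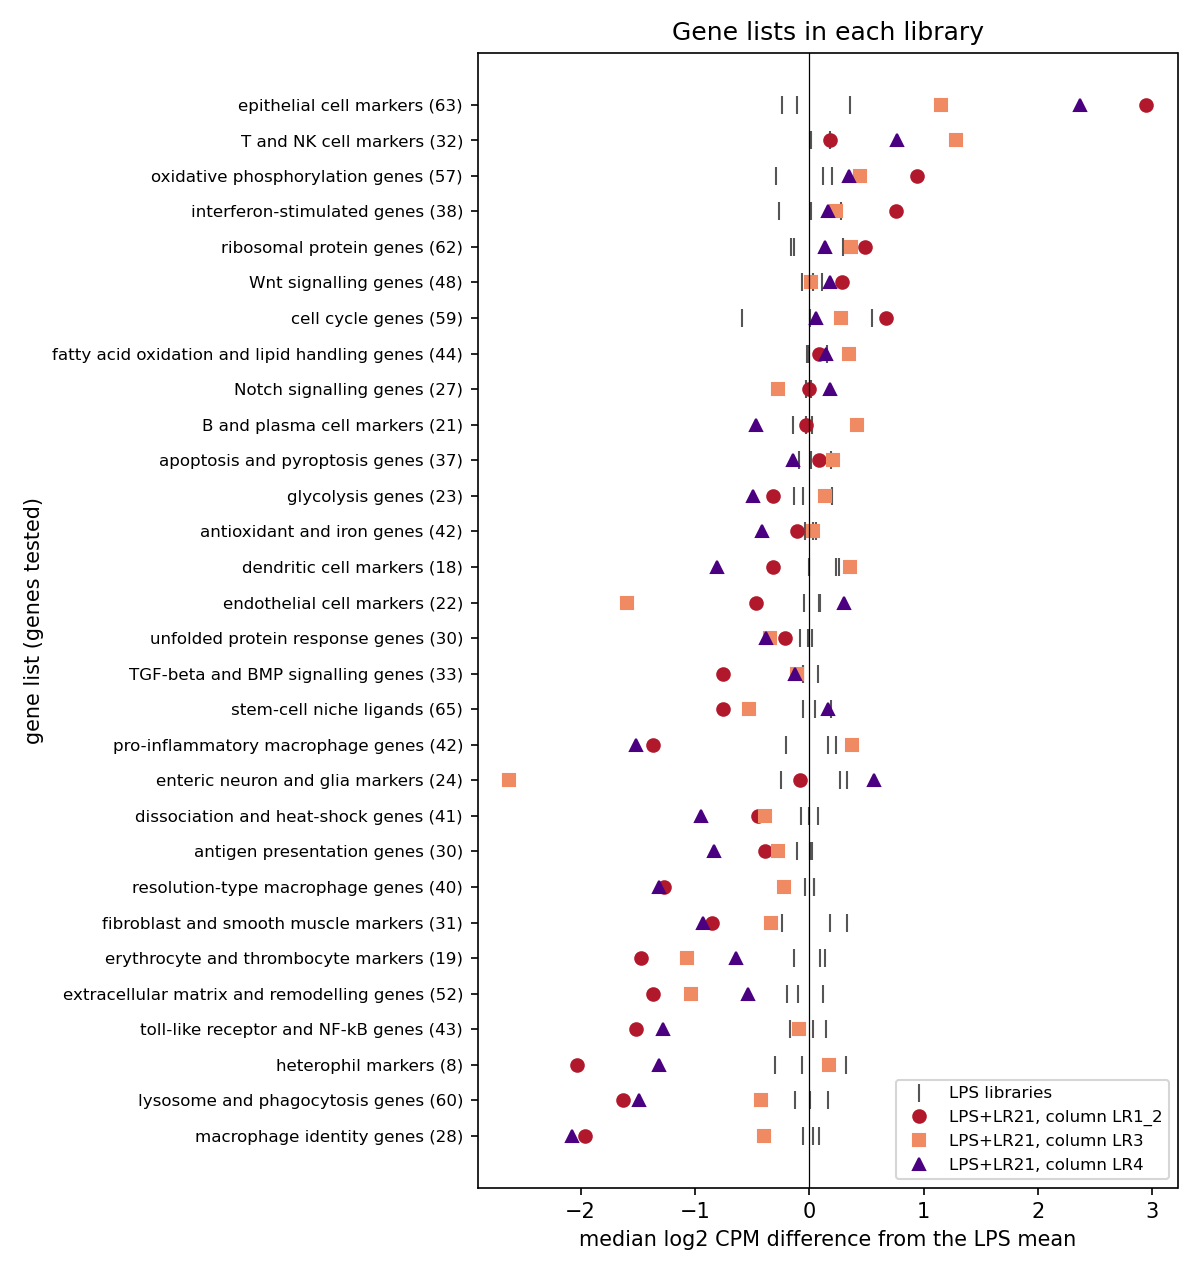
For each fixed gene list (number of tested genes in brackets), symbols show each library's median over the list's genes of log2 CPM minus the mean of the 3 LPS libraries; grey ticks are LPS libraries and coloured symbols the 3 LPS+LR21 libraries. Epithelial markers are highest in LR1_2 (2.94) and LR4 (2.37) and macrophage identity genes are lowest in the same libraries (-1.96 and -2.07), with LR3 nearer to the LPS libraries in both.

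All 28 measured macrophage identity genes had a fitted log2 fold change below 0, with a median of -1.25, while only VSIG4 passed the test; adjusted over the list alone, 9 were lower. The list was called lower by camera (adjusted p = 3.82e-14; adjusted p = 0.330 with an estimated correlation; adjusted p = 0.0997 by fry). With the mean level of the epithelial markers as a covariate, a setting chosen after the data had been seen, camera called the list higher (adjusted p = 0.0111; adjusted p = 0.736 with an estimated correlation), and with LR3 as the only LPS+LR21 library, chosen likewise, it did not call it (adjusted p = 0.136). Of the variance of the epithelial covariate, 79.0% lay between the groups. The fit with it therefore separates group from epithelial content poorly, for this and the other lists. VSIG4, a complement receptor of tissue macrophages (ENSGALG00010016807, chromosome 4, 224999 to 237379, minus strand), fell from 169 ± 43.0 to 50.3 ± 9.91 FPKM (SD, n = 3 each; adjusted p = 0.0435, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CSF1R, the receptor for macrophage colony-stimulating factor (ENSGALG00010016804, chromosome 13, 12876768 to 12897373, plus strand), had 309 ± 35.3 FPKM in the LPS libraries and 106 ± 54.2 in the LPS+LR21 libraries, which did not pass (log2 fold change -1.64 ± 0.44 SE, adjusted p = 0.127). CD14, a co-receptor for LPS, and CYBB, a subunit of the phagocyte oxidase, had log2 fold changes of -1.56 and -1.80 and did not pass. The mannose receptor family includes the antigen of the sorting antibody. Its member MMR1L4, listed as a synonym of MRC1L-B in the RefSeq table, had 13.9 ± 3.69 FPKM in the LPS libraries and 5.93 ± 4.26 in the LPS+LR21 libraries (adjusted p = 0.339), and MMR1L3 had a log2 fold change of -1.10 (adjusted p = 0.558); neither passed. MRC1 and MRC2 were low, at 0.0993 and 0.109 FPKM in the LPS libraries and 0.106 and 0.0460 in the LPS+LR21 libraries. MRC1 had no count in LPS1 and LR3, and MRC2 had none in LR3. Reads shared among these similar receptor genes could be split differently by the counting, so their values are uncertain. The list's median against the LPS mean was -1.96 in LR1_2, -0.39 in LR3 and -2.07 in LR4, and LR3 was nearest to the LPS libraries, as for the epithelial markers. Of the 60 lysosome and phagocytosis genes, 56 had fitted values below 0 (median -1.08), and none passed over all genes whereas 28 were lower adjusted over the list alone. That list was called lower by camera (adjusted p = 3.94e-19; adjusted p = 0.330 with an estimated correlation), and its direction turned to higher with the epithelial covariate (adjusted p = 0.0801). The cysteine protease gene CTSS had 1814 ± 609.9 FPKM in the LPS libraries and 695 ± 345 in the LPS+LR21 libraries, the ganglioside activator gene GM2A had 1775 ± 599 FPKM in the LPS libraries and 539 ± 254 in the LPS+LR21 libraries, and the scavenger receptor gene MARCO had a log2 fold change of -1.74; none of the 3 passed.

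**Figure D3:**
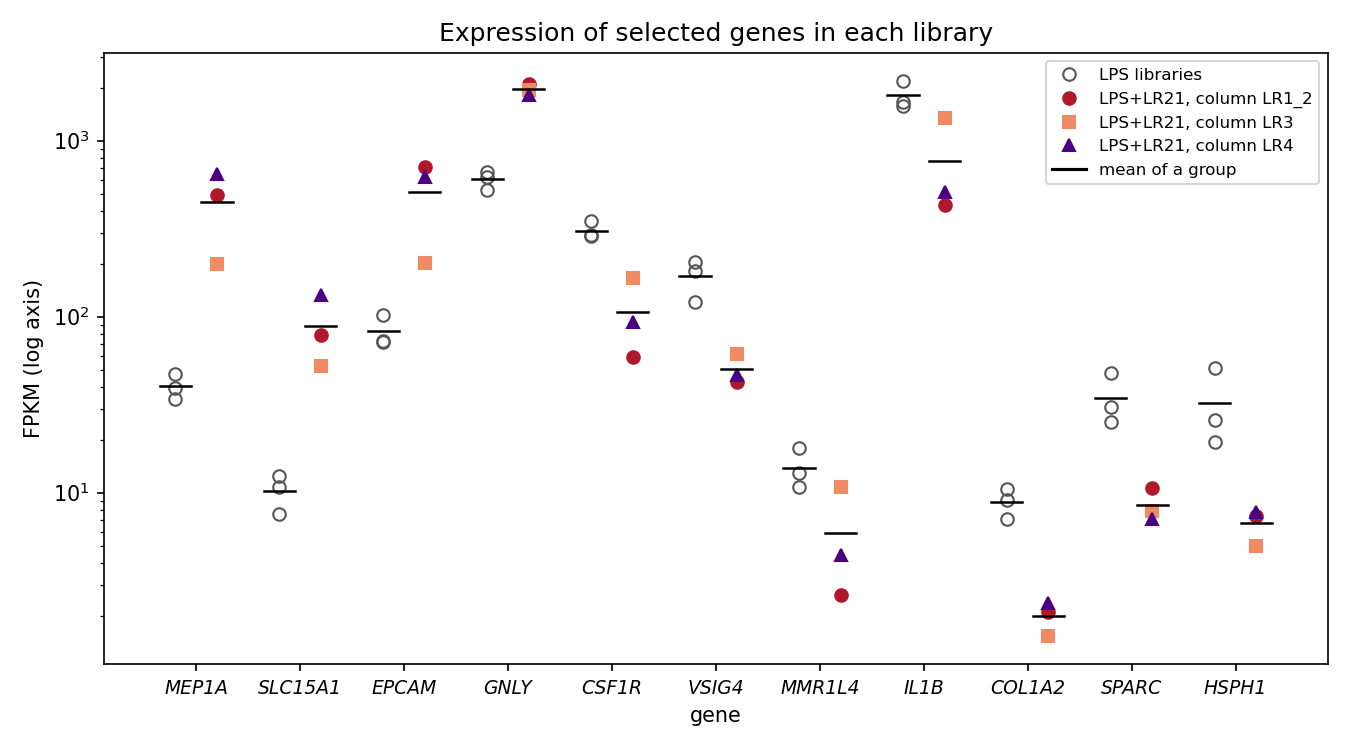
FPKM of 11 genes in each library on a log axis, with open circles for the LPS libraries, filled symbols for the 3 LPS+LR21 libraries and black bars for group means. MEP1A, SLC15A1 and EPCAM rose and VSIG4, COL1A2, SPARC and HSPH1 fell, whereas GNLY, CSF1R, MMR1L4 and IL1B did not pass the test. LR3 lies nearest to the LPS libraries for CSF1R, MMR1L4 and IL1B, and also for VSIG4, MEP1A and EPCAM.

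Inflammatory genes of macrophages tended to have lower fitted values, with no single gene passing. Of 42 pro-inflammatory macrophage genes, 29 were fitted below 0 and 13 above it (median -0.54); none passed over all genes, and none adjusted over the list alone. Camera called this list lower (adjusted p = 0.0174; adjusted p = 0.555 with an estimated correlation), while its median against the LPS mean was -1.36 in LR1_2, 0.37 in LR3 and -1.52 in LR4. With the epithelial covariate the list was called higher (adjusted p = 1.75e-11; adjusted p = 0.309 with an estimated correlation), and it was not called without LPS3, LR1_2 or LR4 (adjusted p = 0.0715, 0.145 and 0.585) or scaled to the macrophage identity genes (adjusted p = 0.201). IL1B, which encodes the inflammatory cytokine interleukin 1 beta, had 1808 ± 334 FPKM in the LPS libraries and 762 ± 504 in the LPS+LR21 libraries (log2 fold change -1.33 ± 0.51 SE, adjusted p = 0.308). IL6 and NOS2, the inducible nitric oxide synthase gene, had log2 fold changes of -1.09 ± 1.17 and -0.56 ± 1.10 (SE), which were within the spread between replicates. The matrix metalloproteinase genes MMP1 and MMP10 had -2.76 and -1.79, and the chemokine gene CCL5 had 1.09; none passed. The toll-like receptor and NF-kB list was called lower (median -0.85, adjusted p = 9.04e-06; adjusted p = 0.445 with an estimated correlation), with none of its 43 members passing and 2 lower adjusted over the list alone. Its median against the LPS mean was -1.51 in LR1_2, -0.09 in LR3 and -1.28 in LR4, and its direction turned to higher with the epithelial covariate (adjusted p = 7.36e-07; adjusted p = 0.361 with an estimated correlation) and with LR3 alone (adjusted p = 0.334). Scaled to the macrophage identity genes it was not called (adjusted p = 0.272). TLR4, the LPS receptor gene, had a log2 fold change of -1.45 ± 0.64 (SE, adjusted p = 0.413), NOD1 had -2.49 and RIPK2 had -1.92. The resolution-type macrophage list was also called lower (median -0.74, adjusted p = 3.98e-05; adjusted p = 0.229 with an estimated correlation), with none of its 40 members passing over all genes; adjusted over the list alone, 2 were higher and 6 lower. It too turned to higher with the epithelial covariate (adjusted p = 0.0617), and it was not called with LR3 alone (adjusted p = 0.495). IL10, an anti-inflammatory cytokine gene, had a log2 fold change of 0.31 ± 0.88 and TGFB1 of -0.61 ± 0.97 (SE), and neither difference exceeded the spread between replicates. Of the 30 antigen presentation genes, DMB1, which encodes a class II peptide-loading chaperone, rose by 2.52 on the log2 scale (adjusted p = 0.0380) although the list was called lower (median -0.74, adjusted p = 0.0170; adjusted p = 0.445 with an estimated correlation). DMB1 was also the 1 member past the threshold adjusted over the list alone. It had 273 FPKM in LR1_2, 106 in LR3 and 210 in LR4, the library order of the epithelial markers, and its source cells were not tested. The list turned to higher with the epithelial covariate (adjusted p = 0.186), with LR3 alone (adjusted p = 0.693) and scaled to the macrophage identity genes (adjusted p = 0.964), and it was not called without LR4 (adjusted p = 0.466). The class II gene BLB1 had -1.25 and CD1B had -1.86, neither of which passed.

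Ligands that could reach intestinal stem cells were measured with no call in the main test. None of the 65 stem-cell niche ligands passed over all genes or adjusted over the list alone, and the list was not called (median -0.49, camera adjusted p = 0.180). EREG and AREG, which encode the growth factors epiregulin and amphiregulin, had log2 fold changes of 2.07 ± 0.59 (adjusted p = 0.148) and 1.51 ± 0.56 (adjusted p = 0.283; SE). For both, LR3 lay within the LPS range while LR1_2 and LR4 lay above it. IL22, which encodes a cytokine acting on epithelium, had 0.225 ± 0.0917 FPKM in the LPS libraries and 1.83 ± 1.02 in the LPS+LR21 libraries (adjusted p = 0.288). GAS6, a ligand of receptors for apoptotic-cell uptake, had a log2 fold change of -2.40 ± 0.51 (adjusted p = 0.0638), PDGFB had -1.16 and WNT5A had -1.91; none passed. The Wnt (median 0.25, adjusted p = 0.180), Notch (median 0.06, adjusted p = 0.893) and TGF-beta and BMP (median -0.34, adjusted p = 0.319) signalling lists were not called, and no member passed in them, adjusted over the list alone included. Their members of smallest p, none past the threshold, were NKD1 (-2.12), FZD5 (1.54), HEY2 (2.53), NOTCH2 (-1.42), ID2 (0.87) and SMAD7 (-1.40), with log2 fold changes in brackets.

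The fallen genes included collagens and a heat-shock gene. COL1A2 (ENSGALG00010003307, chromosome 2, 23456131 to 23515037, plus strand) had 8.86 ± 1.67 FPKM in the LPS libraries and 1.99 ± 0.425 in the LPS+LR21 libraries (SD, n = 3 each), a log2 fold change of -2.30 ± 0.30 (SE, adjusted p = 0.0344). COL3A1 fell by 2.40 and SPARC, a collagen-binding matrix protein gene, fell by 2.13 on the log2 scale. These were the 3 members that passed of the 52 extracellular matrix and remodelling genes, over all genes and adjusted over the list alone (median -0.82, camera adjusted p = 1.03e-05; adjusted p = 0.229 with an estimated correlation; adjusted p = 0.0369 by fry), and the list was not called with the epithelial covariate (adjusted p = 0.181). The 31 fibroblast and smooth muscle markers, with both collagens among them as the 2 that passed on either count, were called lower as well (median -0.76, adjusted p = 0.0258; adjusted p = 0.229 with an estimated correlation). This call was lost without LR4 (adjusted p = 0.206), with library quality weights (0.0561) and with limma-trend on log2(FPKM + 0.1) or log2(FPKM + 1) (0.0927 and 0.0907). It was also lost with the epithelial covariate (0.320), with LR3 alone (0.276) and scaled to the macrophage identity genes (0.0616). ACTG2 and COL6A2 in that list had 2.60 and 1.65 and did not pass. HSPH1, a chaperone of the Hsp110 family, had 32.1 ± 16.6 FPKM in the LPS libraries and 6.70 ± 1.51 in the LPS+LR21 libraries and fell by 2.41 on the log2 scale. It was the 1 called member of the 41 dissociation and heat-shock genes, with 5 lower adjusted over the list alone (median -0.63, camera adjusted p = 1.03e-05; adjusted p = 0.229 with an estimated correlation). The heat-shock list was not called with the epithelial covariate (adjusted p = 0.320), with LR3 alone (0.184) or scaled to the macrophage identity genes (0.630). BAG3 and NR4A3 had -2.81 and -1.62 there, without passing. The other fallen genes under the naming rule were PPP1R3C, a glycogen-targeting phosphatase subunit (-2.41), the metalloprotease gene ADAM19 (-2.31), C3orf70 (-2.09), the phospholipid flippase gene ATP10D (-1.93) and the lactosylceramide synthase gene B4GALT6 (-1.92), with log2 fold changes in brackets. Adjusted p of the 10 fallen genes named lay between 0.0344 and 0.0435 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Erythrocyte and thrombocyte markers were called lower (median -0.81 over 19 genes, adjusted p = 0.00467; adjusted p = 0.229 with an estimated correlation) with no member passing and 1 lower adjusted over the list alone. The list was not called with the epithelial covariate (adjusted p = 0.973) or with LR3 alone (0.136). The haemoglobin gene HBA1 had no count in any LPS+LR21 library and was at least 46.2-fold lower there against a floor of 3 counts per library (adjusted p = 0.0607). That limit rests mostly on LPS3, since HBA1 had 24, 74 and 321 counts in the 3 LPS libraries.

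Several lists were called higher without any member passing over all genes. T and NK cell markers had a median of 0.73 over 32 genes (adjusted p = 1.90e-04; adjusted p = 0.330 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. GNLY and GZMA, which encode cytotoxic granule proteins, and the T cell transcription factor gene BCL11B had log2 fold changes of 1.57, 1.48 and 1.53, and PDCD1 had -1.80. This list's order among libraries differed from that of the epithelial markers, with 0.18 in LR1_2, 1.28 in LR3 and 0.77 in LR4. Oxidative phosphorylation genes had a median of 0.60 with 54 of 57 fitted above 0 (adjusted p = 3.16e-11; adjusted p = 0.445 with an estimated correlation). Ribosomal protein genes had 0.32 with 60 of 62 above 0 (adjusted p = 1.46e-05; adjusted p = 0.555 with an estimated correlation). Interferon-stimulated genes had 0.34 (adjusted p = 0.0340; adjusted p = 0.555 with an estimated correlation) and cell cycle genes 0.22 (adjusted p = 0.0484; adjusted p = 0.711 with an estimated correlation). Without LR3 the T and NK cell list was not called (adjusted p = 0.108). The interferon call was lost without LR3, LR1_2 or LPS2 (adjusted p = 0.223, 0.345 and 0.178), with quantile normalization (0.126), at a mean of at least 5 FPKM (0.754), with limma-trend on log2(FPKM + 0.1) or log2(FPKM + 1) (0.385 and 0.370) and with the epithelial covariate (0.511). The cell cycle call was lost without LR3, LR1_2, LPS1 or LPS2 (adjusted p = 0.108, 0.397, 0.788 and 0.0726), with LR3 alone (0.122), with DESeq2 (0.167), with quantile normalization (0.0997), and at a mean of at least 5 FPKM (0.754). It was also lost with both limma-trend settings (0.477 and 0.479) and with the epithelial covariate (0.320). Of the 16 lists called in the main test, 3 kept their call with the epithelial covariate, 7 lost it in the same direction and 6 changed direction. The 3 that kept it were among the epithelial, T and NK cell, oxidative phosphorylation and ribosomal protein lists. The remaining list of these lost it. With an estimated correlation, camera called none of these in that fit (adjusted p = 0.554, 0.309, 0.876 and 0.785, in the same order). Among oxidative phosphorylation, ribosomal protein, interferon-stimulated and cell cycle genes no member passed adjusted over the list alone either. Their members of smallest p included NDUFAB1 (0.90), RPL35 (0.69), HELZ2 (2.12), GBP (-2.30), TK1 (2.36) and PCNA (-0.81), with log2 fold changes in brackets.

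Among the lists that were not called, FAS, a death receptor gene, rose by 1.60 on the log2 scale (adjusted p = 0.0397) within 37 apoptosis and pyroptosis genes, where 6 were higher adjusted over the list alone. NQO1, a quinone reductase gene, rose by 2.55 (adjusted p = 0.0435) within 42 antioxidant and iron genes, of which 3 were higher and 2 lower adjusted over the list alone. Of the 44 fatty acid oxidation and lipid handling genes none passed over all genes, and 6 were higher and 3 lower adjusted over the list alone; ACSL5 and PPARA had log2 fold changes of 2.20 and 2.23. 1 member each was higher adjusted over the list alone among glycolysis genes, B and plasma cell markers, where PIGR had 2.14 and PRDM1, lower on the same count, -1.21, and enteric neuron and glia markers, where S100B had 3.70 and FABP7, lower on the same count, -1.29. PIGR had 157 FPKM in LR1_2, 46.1 in LR3 and 105 in LR4, the library order of the epithelial markers. PIGR did not pass over all genes (adjusted p = 0.0527, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and which cells its transcripts came from was not tested. FAS and NQO1 had the same library order, highest in LR1_2 and lowest in LR3. Unfolded protein response genes (HSPA5 -1.79, CHAC1 1.64), heterophil markers (CXCR1 -1.38, CSF3R -1.32), dendritic cell markers (IRF4 1.22, ID2 0.87) and endothelial markers (CDH5 2.09, EGFL7 -1.41) had no member past the threshold on either count, with log2 fold changes given. Camera adjusted p of the 14 lists not called lay between 0.0906 and 0.922. Some of the 14 were called in the same direction under other settings at the preset correlation. Among fits with replicates in both groups, each limma-trend setting called 5 and the epithelial covariate 5. Scaling to the macrophage identity genes called 4 and quantile normalization 2. DESeq2, library quality weights and a mean of at least 5 FPKM called 1 each, as did leaving out LR1_2, LR3 or LR4. The median and the mean differed in sign for glycolysis, apoptosis, B cell and dendritic cell lists, and the median and the direction of the test for the Notch, apoptosis, antioxidant and B cell lists.

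In all, camera called 16 of the 30 lists, 6 higher and 10 lower, none of them with an estimated correlation, and fry called 4, all lower: the heat-shock, extracellular matrix, fibroblast, and erythrocyte and thrombocyte lists. The 219 calls depended on the libraries included: without any 1 of the 3 LPS libraries, without LR1_2 or without LR4 edgeR called 0 genes (1643 to 2764 at an unadjusted p under 0.05), and without LR3 it called 1945, 1086 higher and 859 lower. With LR3 alone, where only the LPS libraries give the spread, edgeR called 0 genes (3798 at an unadjusted p under 0.05), and camera called the pro-inflammatory list higher at the preset correlation (adjusted p = 0.00819) and not with an estimated correlation (adjusted p = 0.470).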

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

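The settings with log2(FPKM + 1), plain limma-voom, the epithelial score, scaling to macrophage identity genes and LR3 alone, and the estimated correlation in the last 3 of these, were chosen after the data had been seen. No paired analysis was possible because the numbers in the names of the LPS+LR21 columns do not pair off with those of the LPS columns, and for the same reason the replicate number was not tried as a block. The 219 changed genes (202 higher, 17 lower) stayed within 1.5 times with no filter, library totals, DESeq2 size factors and robust estimation, under which at least 213 of the 219 were called again in the same direction. More genes passed with DESeq2 (1361; 1002 higher, 359 lower), plain limma-voom (366; 305 and 61), limma-voom with library quality weights (1956; 1060 and 896), limma-trend on log2(FPKM + 1) (477; 415 and 62) and on log2(FPKM + 0.1) (438; 386 and 52), and a mean of at least 5 FPKM (434; 326 and 108), where fewer genes were tested. Quantile normalization in limma-voom gave 135 (109 and 26), of which 112 were among the 219. At an unadjusted p under 0.05 there were 2502 (1547 and 955), and 2053 (1315 and 738) with at least a 2-fold change.

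Leaving out each library in turn gave 0 to 1945 changed genes, 0 to 1086 higher and 0 to 859 lower. The cause was not tested. Only the fit without LR3 gave any, and all 219 were among its calls. The other 5 fits gave 0 with edgeR, with 1643 to 2764 genes at an unadjusted p under 0.05, and all 219 genes had the same sign as with all 6 libraries. With LR3 as the only LPS+LR21 library, which is assumed to vary like the others, edgeR called 0 changed, 0 higher and 0 lower (3798 at an unadjusted p under 0.05). With the epithelial score as a covariate it called 0, 0 and 0 (1876 at an unadjusted p under 0.05), and 218 of the 219 genes had the same sign. Scaled to the macrophage identity genes 4784 changed (4780 higher and 4 lower), because that scaling moved the median log2 fold change of all genes from -0.14 to 1.42; library totals moved it to 0.02, and limma-voom gave -0.24 and quantile normalization -0.04. Under that scaling the 17 fallen genes had a median of -0.61, and edgeR called 0 of them (7433 genes of all were at an unadjusted p under 0.05).

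Camera called 14 to 18 lists, against 16, under the settings run with the preset correlation, and 14 or 15 when a library was left out. It called 0 with an estimated correlation, and fry called 4. With an estimated correlation it also called 0 in the fits with the epithelial score, LR3 alone and the identity scaling (smallest adjusted p 0.309, 0.470 and 0.599, with 4, 1 and 1 lists at an unadjusted p under 0.05). The direction of some lists turned, and those called in at least 1 of the compared fits were as follows. With the epithelial score as a covariate these turned up: pro-inflammatory (adjusted p = 1.75e-11), toll-like receptor and NF-kB (7.36e-07), dendritic cell (0.000397), glycolysis (0.00309), heterophil (0.00317), macrophage identity (0.0111), resolution-type (0.0617), lysosome (0.0801) and antigen presentation (0.186). With LR3 alone pro-inflammatory (0.00819), dendritic cell (0.00819), glycolysis (0.0218), toll-like receptor (0.334) and antigen presentation lists (0.693) turned up. Scaled to macrophage identity genes, glycolysis (0.0277), unfolded protein response (0.0285) and antigen presentation (0.964) turned up. Among lists called in neither fit, Notch and TGF-beta and BMP turned up in all 3 settings, heterophil with LR3 alone (0.487) and dendritic cell with the identity scaling (0.331). The cause was not tested. In simulated data of this spread edgeR called 0% of 67 genes changed 2-fold (DESeq2 10.4%), so changes of that size can be missed here.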

Other observations

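The tests of macrophage identity genes, of pro-inflammatory genes and of a change within the macrophages themselves were chosen after the results had been seen, as were the settings that use the epithelial score, the identity genes or LR3 alone.

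Lipid and sugar handling genes of enterocytes were among the risen genes: APOB and MTTP, which serve lipoprotein assembly, rose by 2.63 and 2.66 on the log2 scale, the glucose transporter gene SLC5A1 by 3.00 and the fatty acid binding protein gene FABP1 by 2.46 (adjusted p 0.0373 to 0.0422, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The crypt marker genes OLFM4 and LGR5 had 12.6 and 1.41 FPKM on average in the LPS libraries and 67.9 and 6.34 in the LPS+LR21 libraries, and neither passed (adjusted p = 0.0640 and 0.168).

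The called collagen genes differed in their order among the LPS+LR21 libraries. COL1A2 had 2.10 FPKM in LR1_2, 1.53 in LR3 and 2.35 in LR4, against 7.10 to 10.4 in the LPS libraries, and COL3A1 had 3.19 in LR1_2, 5.04 in LR3 and 4.19 in LR4, against 14.5 to 30.5. The geometric mean of the macrophage identity genes was 28.3% of the LPS mean in LR1_2, 69.6% in LR3 and 26.6% in LR4.

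The 202 risen genes may reflect more epithelial RNA in the LPS+LR21 libraries. Over the 183 of them outside the epithelial list, the median within-group correlation with each library's epithelial score was 0.878 (against a 95% range of -0.405 to -0.0612 in 1000 random sets of uncalled genes of matched level). Most of the score's within-group spread lay in LPS+LR21 (SD 0.844 against 0.196 in LPS). There LR3 was lowest, at 5.40 against 7.03 in LR1_2 and 6.59 in LR4, so the correlation rests largely on that library. The random sets vary genes and not libraries, and a rise within the macrophages that was weaker in LR3 would give a similar value. The enterocyte gene FABP2, which did not pass, had 231 FPKM in the LPS and 2003.5 in the LPS+LR21 libraries, although a KUL01 sort should remove epithelial cells. With the score as a covariate the median log2 fold change of the 202 genes went from 2.56 to 0.85 (quartiles 0.56 to 1.31) and the median standard error from 0.43 to 0.56. Because 79.0% of the score's variance lies between the groups, a rise within the macrophages themselves cannot be told apart from more epithelial RNA by that fit.

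The lower macrophage identity genes could come from dilution by RNA of other cells. After scaling to the list, 0 of its 28 members differed between groups at an unadjusted p under 0.05 by edgeR's quasi-likelihood test (smallest 0.0570). Scaled log2 fold changes of the 28 ran from -0.61 to 1.74, the highest being that of the low-count gene MRC1 (SE 1.94). The scaling removes the shared part by construction, so the test shows only that the members did not move apart detectably. A uniform decrease of these genes in each macrophage remains open.

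The lower pro-inflammatory list might reflect less inflammatory expression per macrophage, which cannot be told apart from fewer macrophages with these values. Scaled to the identity genes, all 42 members had a median log2 fold change of 0.59 (95% bootstrap interval over genes 0.31 to 1.04). The 29 members with lower fitted values before scaling had a median of 0.28 (0.10 to 0.57). Both intervals resample genes and hold none of the spread between libraries. The same scaling moved the median of all genes from -0.14 to 1.42, so a value above 0 there does not settle the question. If the identity genes themselves were lower in each macrophage, the list could be lower per macrophage as well.

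With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 219 changed genes, 202 higher and 17 lower, and the highest other split gave 0 of each; it called 16 lists, and the highest other split 15. Thus 1 split of the 10, the real one, reached each value. For the lists the real split stood out little. The splits that grouped LPS1, LPS2 and LR3, or LPS1, LPS2 and LR4, or LPS1, LPS3 and LR3 called 14 lists each.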
